A study of Mus musculus with 2 samples.

How the data were processed

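RNA from microdissected embryonic arteries was measured on 2 Affymetrix mouse expression arrays. Per the labels, the vessels came from ICR mouse embryos at embryonic day 13.5, and the design text gives 22 embryos whose segments were pooled. Whether the same embryos gave both vessels is not given in the sources used here. One pool held internal carotid arteries and the other external carotid arteries. Per the labels' protocols, total RNA went through a guanidine extraction with column purification, then a pair of amplification rounds primed with oligo-dT and a biotin-labelled transcription step. The design text states that neither biological nor technical replicates were made, so each group has 1 array.

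The deposited values are linear signal intensities per probe set, made with GCOS 1.4 and MAS5 per the submitters' processing notes. The deposited intensity table holds 45101 probe sets, of which 64 are controls, and no detection calls were used here. The 2% trimmed mean of the deposited intensity was 150 on both arrays, so the arrays had been scaled to a common mean and were used as deposited. Signals reached 14469 on the internal carotid array and 10316 on the external carotid array, and 1 value, on the internal carotid array, was 0. Because amplification started from the poly-A tail and was repeated, signals favour the 3' ends of transcripts, and small differences in input can be enlarged.

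Probe sets were named through the platform annotation, with symbols updated by gene number through a RefSeq table (GRCm38.p6, used for names only). Of 45037 non-control probe sets, 34945 had 1 gene, 932 had several and 9160 were not listed in that annotation. The gene number matched the RefSeq table for 34741 of the 34945, and the other 204 kept the annotation's symbol. Names were taken only from probe sets with 1 gene. A gene was represented by its brightest probe set, which gave 18193 genes.

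The ratio is external over internal carotid signal on the log2 scale. Each array's median over non-control probe sets served as a floor, 47.5 for internal and 52.3 for external carotid. Where both signals reached the floor, the ratio was used. Where 1 side was under it, the other side's signal over that floor gave a lower bound, written as at least N-fold. Where both sides were under it, no fold was given. A bound that pointed opposite to the measured side also gave no fold, a rule set after the data were examined. A ratio or bound was had for 12408 genes.

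With 1 array per group there is no spread between samples and no p-value is given. As a technical spread, the standard deviation of log2 ratios between probe sets of one gene was pooled over 4315 genes with 10950 probe sets. It was 0.34, or 1.26-fold, and covers probe differences on the same pair of arrays, not differences between embryos or dissections. Genes are called higher at 2-fold. The number of arrays limits the precision of every value.

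Before the data were examined, 39 gene lists were fixed, covering the endothelin system, guidance and signalling families, positional genes, cell types and cell states. For each list the median log2 ratio over measured members was computed, with bounds at their bound. Its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins, describes where the list stands on these 2 arrays and is not a test across animals. Named genes also followed a rule fixed beforehand. They are the endothelin genes, the 15 genes per direction with the largest ratio whose measured probe sets shared a sign, the 5 largest bounds per direction, the 2 highest and 2 lowest members of each list, and up to 4 of the most abundant members of cell type lists. Cplx1 was passed over for probe sets of opposite sign, and 232 genes were named by the rule.

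The steps were tested on simulated data made from these 2 arrays, with 50 genes changed at each fold size among 12249 genes. At the 2-fold threshold 58% of genes changed by 2-fold were called, 98% at 3-fold, 98% at 4-fold and 100% at 8-fold, as were 41 of 12049 unchanged genes. Of 100 unchanged lists of 20 genes, 4 lay outside the central 95% of random lists. These lists were drawn at random with independent noise, so a share of about that size was fixed in advance. The simulated noise had the probe-set spread of 0.34 at every signal level. It held no difference between pools, dissections or amplifications, so the rates are not error rates of the real comparison.

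Alternatives changed one choice at a time. They were centring on the median, quantile normalization, loess of the ratio on mean signal with a span of 0.3, a floor at the 25th or 75th percentile, no floor, a pseudocount at the floor, the median over a gene's probe sets, leaving out probe sets marked as open to cross-hybridisation, 1.5-fold and 3-fold thresholds, counting probe sets, and lists restricted to members measured on both arrays. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Ednra has no probe set with 1 gene in the annotation used and was not analysed here.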

Results

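Expression was compared between a pool of internal carotid arteries and a pool of external carotid arteries from mid-gestation mouse embryos. The series concerns endothelin in the pathfinding of axons from the superior cervical ganglion, the sympathetic ganglion whose axons follow these vessels, so the comparison asks which genes differ between the 2 branches. There was 1 array per pool and no replicate, so every value below is a single measurement per vessel. Signals of the 45037 non-control probe sets had a Spearman correlation of 0.94 between the arrays, across probe sets, which are not independent replicates.

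Both arrays carried RNA with signal weighted to the 3' end. The 3' over 5' signal ratio of Actb was 4.41 on the internal and 3.53 on the external carotid array, and that of Gapdh was 8.39 and 7.09. The 18 bacterial hybridisation control probe sets had a median log2 ratio of -0.45, external over internal, with a range of -0.66 to -0.16. Among probe sets measured on both arrays the median log2 ratio ran from 0.17 in the dimmest of 10 equal groups by mean signal to -0.19 in the brightest.

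Of 12408 genes with a ratio or bound, 261 were at least 2-fold higher in the external carotid pool and 183 in the internal carotid pool, while 96.4% had a ratio or a lower bound under 2-fold. The external excess depended on scaling, with 196 external-high and 230 internal-high genes after loess, 203 and 219 after quantile normalization, and 222 and 218 after centring. The genes highest in the external carotid pool included several that catecholamine-making neurons express. Dbh, which makes noradrenaline from dopamine, was 21.2-fold higher, the neuropeptide precursor gene Cartpt 20.9-fold, and Th, the rate-limiting enzyme of catecholamine synthesis, 9.83-fold. The internal carotid signals of Cartpt and Th, 52.6 and 58.4, stood near the floor of 47.5. Further neuronal and secretory genes followed, with Ina 9.72-fold, Cyb561 7.42-fold, Pcsk1n 6.77-fold, Prph 5.28-fold, Nefl 5.11-fold, Chga 4.92-fold and Stmn3 4.90-fold higher. These folds are those of the brightest probe set, and the lowest log2 ratio among measured probe sets was 2.21 for Dbh, 2.17 for Ina, 1.61 for Stmn3 and 0.18 for Prph. Genes on no neuronal list were also among them, including the matrix protein gene Ltbp2 at 16.6-fold, the peptidase gene Mme at 8.86-fold, Tlcd3b at 5.79-fold and the secretoglobin gene Scgb3a2 at 5.19-fold. Of genes measured only in the external carotid pool, Slc6a2, the noradrenaline transporter, was at least 12.1-fold higher by its brightest probe set, with 0.34 on the log2 scale as the lowest of 4, Crh at least 3.88-fold, Brsk2 at least 3.52-fold, Pantr1 at least 3.37-fold and Celf5 at least 3.36-fold. With the floor at the 75th percentile the bounds of Crh, Brsk2, Pantr1 and Celf5 were under 2-fold, and with the median over probe sets Slc6a2 and Prph were under 2-fold.

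The genes highest in the internal carotid pool included many sarcomere and other muscle genes. Myom2 was 10.4-fold higher, Mybph 8.01-fold, Myh7 7.48-fold, the calcium release channel gene Ryr1 7.32-fold, Myh3 6.80-fold and Neb 6.45-fold. Mymx, needed for myoblast fusion, was 6.12-fold higher, Pitx3, a transcription factor also made in embryonic muscle, 7.04-fold, Actn2 5.79-fold, Csrp3 5.71-fold and Synpo2l 5.68-fold. The measured probe set nearest 0 was at -1.50 for Ryr1 and -1.09 for Synpo2l. Outside that class were the dermatopontin gene Dpt at 12.0-fold, the neutrophil genes S100a8 at 11.9-fold and Ngp at 6.30-fold, and Med18 at 7.58-fold. The external carotid signals of Dpt, Csrp3 and Neb, 53.8, 59.3 and 63.6, stood near the floor of 52.3. Among genes measured only in the internal carotid pool, Il17b was at least 7.53-fold higher, Myh8 at least 7.02-fold, Chrng at least 4.85-fold, Myh1 at least 4.62-fold and Cfap61 at least 4.24-fold, and the bounds of Chrng, Myh1 and Cfap61 were under 2-fold with the floor at the 75th percentile. Where a gene had a further measured probe set, it shared the sign in 48 of 55 external-high and 33 of 44 internal-high genes, against 2467 of 4315 genes of any ratio. That further probe set reached 2-fold in 16 of the 55 and 10 of the 44, so the fold of a single gene depends on its probe set.

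**Figure D1:**
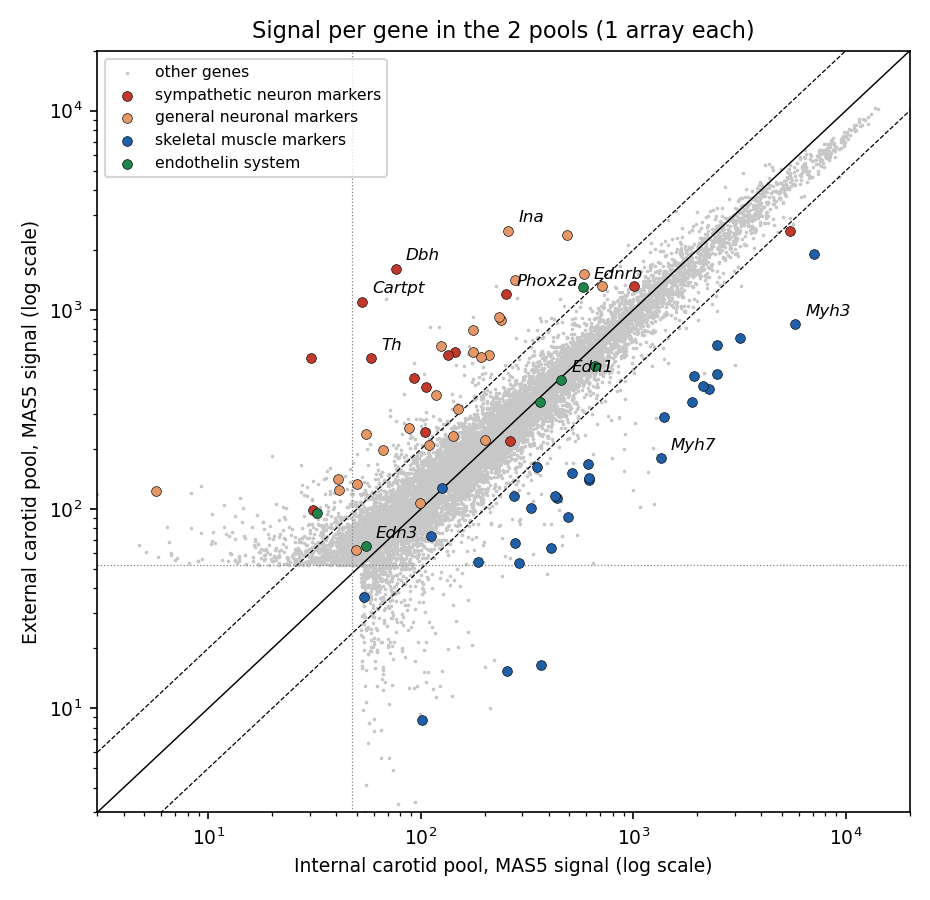
MAS5 signal of each gene in the internal carotid pool (x axis, log scale) against the external carotid pool (y axis, log scale), 1 array each; dotted lines are the floors of 47.5 and 52.3, the solid line marks equal signal and dashed lines 2-fold. Sympathetic and general neuronal markers lie mostly above the 2-fold line, skeletal muscle markers mostly below it, and Edn1 and Edn3 near equality.

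Endothelin genes were compared because the series names this ligand family. Edn3, the ligand that acts mainly through the B receptor, had a signal of 65.0 in the external and 55.0 in the internal carotid pool, a 1.18-fold difference, or 0.24 on the log2 scale, which is under the technical spread of 0.34. Both signals stood just above the floors, a further Edn3 probe set read 54.9 and 52.3, and the remaining pair lay under the floors. Edn1 was brighter and near equal, at 442 external and 455 internal (log2 ratio -0.04), and Edn2 lay under both floors at 50.5 and 37.5. Ednrb, the B receptor, was 2.25-fold higher in the external carotid pool (log2 ratio 1.17), with 0.79 and 0.36 at its other probe sets, and the call was lost with the median over probe sets. Of the converting enzymes, Ece1 had a log2 ratio of -0.34, with -0.65 at a further probe set, and Ece2 of -0.09, while Ecel1, a relative found in neurons, was at least 2.02-fold higher in the external carotid pool, a call lost after centring, quantile normalization and loess and with the pseudocount. The 6 measured genes of this list had a median of 0.10, at percentile 65.4 of random lists, and -0.06 with the floor at the 75th percentile, and Ednrb is also on the Schwann cell and neural crest list, whose median was 0.60.

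Sympathetic neuron markers stood highest of the 39 lists. Their median log2 ratio was 2.11 (percentile 100), and 11 of 14 measured members were at least 2-fold higher in the external carotid pool. Phox2a, a transcription factor of noradrenergic neurons, was 4.75-fold higher, and the related regulator Hand2 had a log2 ratio of 0.39. Gata2 had a log2 ratio of -0.25, and Dlk1, which many embryonic tissues express, was the 1 member at least 2-fold higher in the internal carotid pool, with a log2 ratio of -1.13, a call lost after quantile normalization and loess. General neuronal markers had a median of 1.55 (percentile 100), with 20 of 26 at least 2-fold higher in the external carotid pool and all 26 above 0. The adhesion molecule genes L1cam and Ncam1 had log2 ratios of 1.36 and 0.88, while Dcx and Nrcam had the lowest, 0.13 and 0.15.

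Schwann cell and neural crest markers had a median of 0.60 (percentile 100), with 7 of 19 at least 2-fold higher in the external carotid pool. Tfap2b was 4.35-fold higher and Fabp7 3.60-fold, Sox10 had a log2 ratio of 0.63 and Pmp22 of 0.21, and Erbb3 of -0.30. Sensory neuron markers had a median of 0.18 (percentile 63.2), which was -0.04 with the floor at the 25th percentile and -0.02 with the median over probe sets. Prrxl1 and Tlx3 had log2 ratios of 1.34 and 1.06, the former within 2-fold at the 75th percentile floor and the latter after quantile normalization and loess and with the pseudocount, and Pou4f1 and Ntrk3 of -0.55 and -0.47. Together, 38 of the 261 external-high genes were on the sympathetic, general neuronal or Schwann cell lists.

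Skeletal muscle markers stood lowest of the 39 lists, with a median of -2.05 (percentile 0). At least 2-fold higher in the internal carotid pool were 27 of 31 measured members, and none was so in the external carotid pool. The most abundant, the sarcomere genes Actc1, Myh3, Ttn and Tnnc1, had log2 ratios of -1.88, -2.77, -2.13 and -1.90. Myom1 was near equal at 0.03, and Mybpc1, measured only in the internal carotid pool, had a bound of -0.05. These 27 genes were among the 183 internal-high genes.

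Macrophage and leukocyte markers had a median of -0.51 (percentile 0), with 18 of 21 below 0. Tyrobp was 2.01-fold higher in the internal carotid pool, a call lost after quantile normalization and loess and with the pseudocount, and Laptm5, Csf1r and C1qb had log2 ratios of -0.80, -0.54 and -0.51. Erythroid markers had a median of -0.12 (percentile 22.0), with the embryonic globin genes Hbb-y at -0.40, Hba-x at -0.54 and Hbb-bh1 at -0.67. The sign of Hbb-y turned after quantile normalization.

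Among other tissues, cartilage markers had a median of 0.38 (percentile 99.1), with Sox5 at 1.23, within 2-fold with the pseudocount and at the 75th percentile floor, and Col2a1 at 0.75, but lay outside the central 95% of random lists under only 6 of 10 settings. Bone markers had a median of 0.19 (percentile 72.5; -0.08 with no floor), tendon and connective tissue markers 0.04 (percentile 38.7; 99.4 with the floor at the 25th percentile), epithelial markers 0.05 (percentile 24.3), adipocyte markers 0.03 (percentile 52.5) and thyroid, parathyroid and thymus markers 0.45 (percentile 90.6, 4 genes). The tendon, epithelial and adipocyte medians were below 0 after centring, quantile normalization and loess. Single members stood apart. The tendon list held Fmod at 1.14 and Thbs4, at least 2-fold higher in the internal carotid pool, at -1.58, a call lost at the 75th percentile floor. The epithelial adhesion gene Epcam had a log2 ratio of 1.96, read from a probe set open to cross-hybridisation and with no value without it, Krt14 was at -0.94, and Eya1 was at least 2-fold higher in the external carotid pool with a bound of 1.44.

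**Figure D2:**
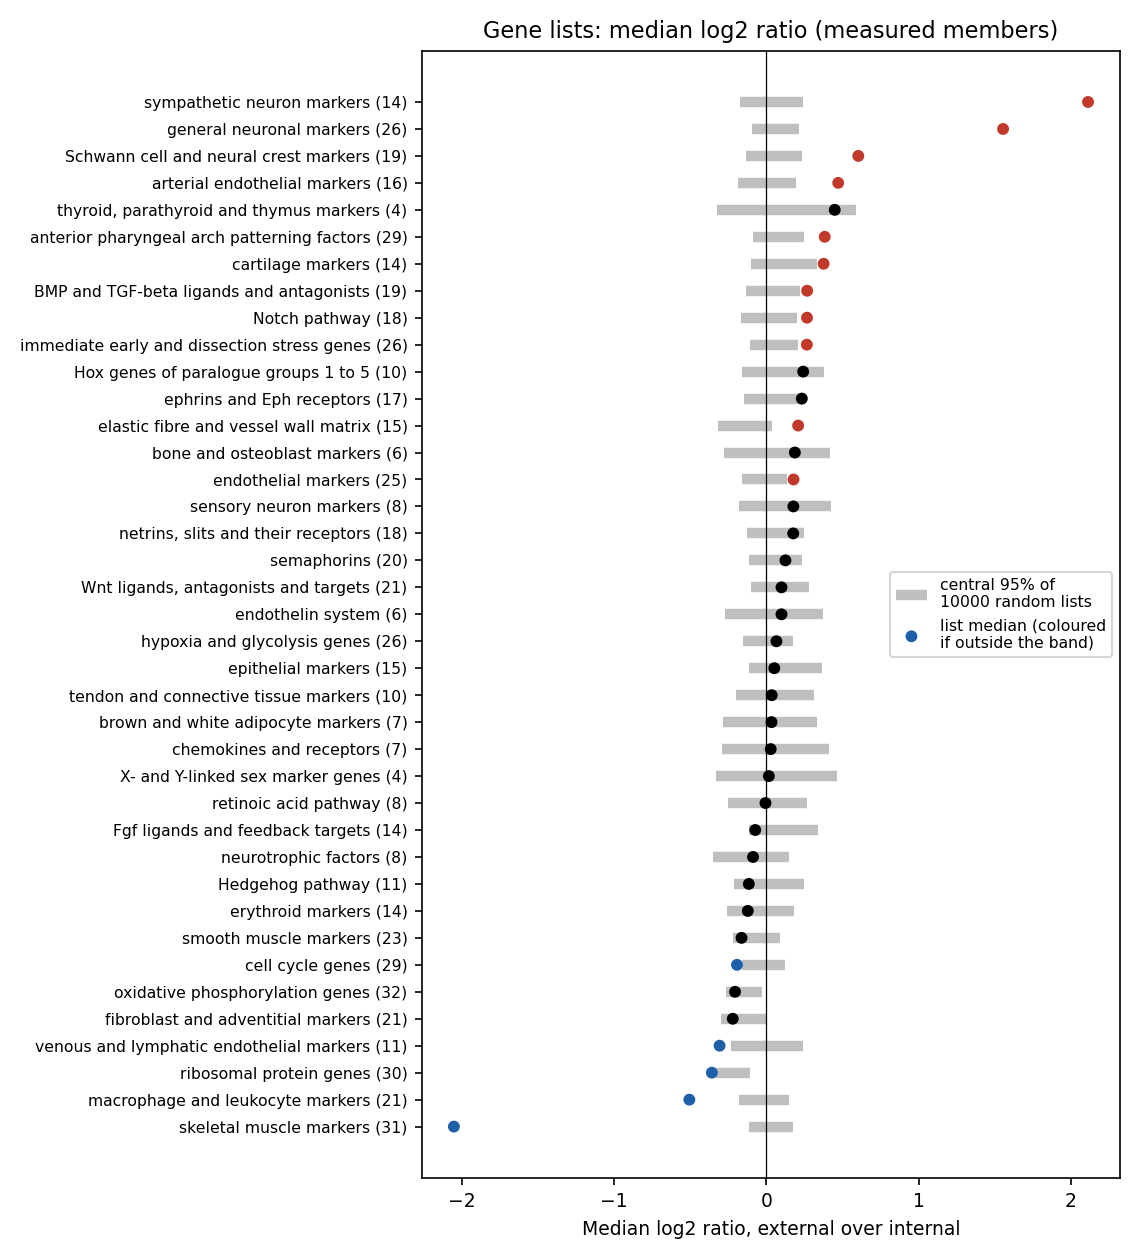
Median log2 ratio, external over internal carotid, of the 39 gene lists (x axis), with the number of measured members in brackets; grey bands show the central 95% of 10000 random lists matched on signal. Sympathetic neuron markers lie at 2.11 and skeletal muscle markers at -2.05, with 11 lists above and 5 below their band. By chance 1.95 in all would be outside if lists shared no genes and the genes within a list varied independently. Genes of one cell type can move together with the make-up of a pool, so that number is no measure of chance between pools.

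Arterial endothelial markers had a median of 0.47 (percentile 100), with 14 of 16 above 0 and none past 2-fold, though 1 was past it, higher in the external carotid pool, after quantile normalization and loess and with the floor at the 25th percentile, and 1 in each direction with no floor. The Notch receptor gene Notch4 had a log2 ratio of 0.99, the Notch target Hey2 of 0.94, Sox17 of 0.54 and the connexin gene Gja4 of 0.41, while Nrp1 was at -0.46 and Unc5b at -0.09. Endothelial markers as a whole had a median of 0.18 (percentile 99.5), with Cd34 2.22-fold higher and Sox18 at 0.74, and Cldn5 at -0.17 and Tal1 at -0.59. Venous and lymphatic markers had a median of -0.31 (percentile 0.53), with 9 of 11 below 0, Nr2f2, a regulator of venous identity, at -0.65, Pdpn at -0.59 and Aplnr at -0.31. The venous list lay within the random range, at percentile 11.7, when a gene's probe sets were summarised by their median. In the same pools the general neuronal markers had a median of 1.55 and the Schwann cell and neural crest markers of 0.60.

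Smooth muscle markers had a median of -0.16 (percentile 9.05), within the random range, but at percentile 0.59 with the median over probe sets. Of the 23 measured members, 10 were above 0 and 13 below. Acta2, the abundant smooth muscle actin gene, had a log2 ratio of -0.45, Pdgfrb of -0.16 and Cald1 of -0.12, the latter pair above 0 after quantile normalization and loess. Myocd, the coactivator of smooth muscle genes, and Lmod1 were highest, at 0.64 and 0.49. Of the 3 members at least 2-fold higher in the internal carotid pool, Des at -2.44 is also on the skeletal muscle list, and Abcc9 was at -1.35, a call lost without probe sets open to cross-hybridisation. Fibroblast and adventitial markers had a median of -0.22 (percentile 17.6), with Col14a1 at 1.26, within 2-fold with the median over probe sets, Thy1 at 0.98, Pdgfra at -0.98 and Col3a1 at -0.36. Dpt, lowest of this list at -3.59, was its 1 member at least 2-fold higher in the internal carotid pool. The fibroblast median and Col3a1 were above 0 after quantile normalization and loess. Elastic fibre and vessel wall matrix genes had a median of 0.21 (percentile 100). None of the 15 passed 2-fold, with Col8a1 at 0.96, Fbln5 at 0.62, the elastin gene Eln at 0.32, Fbn2 at -0.79 and Has2 at -0.49.

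**Figure D3:**
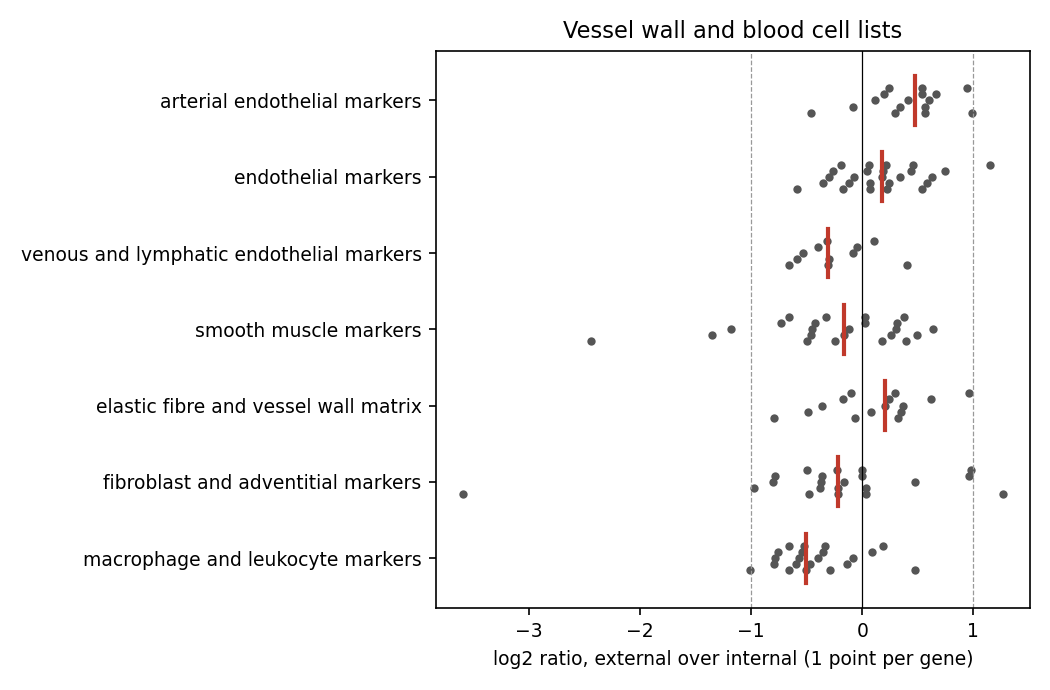
Log2 ratio, external over internal carotid (x axis), of each measured member of 7 vessel wall and blood cell lists, 1 point per gene; red bars mark list medians and dashed lines 2-fold. The arterial median lies at 0.47, the venous and lymphatic median at -0.31 and the macrophage median at -0.51.

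Ligand families that can guide or sustain axons were within the range of random lists. Neurotrophic factors had a median of -0.09 (percentile 55.3; 0.07 with the pseudocount), with Bdnf 2.28-fold higher in the external carotid pool, a call lost with the pseudocount and at the 75th percentile floor, Ptn at 0.15, Igf2 at -0.40 and Igf1 at -0.31. Semaphorins had a median of 0.13 (percentile 73.2), and Sema5a was 2.16-fold higher in the internal carotid pool, a call lost with the median over probe sets, with Sema5b at -0.77, while Sema3d had a bound of 0.58 and Sema3c a ratio of 0.45. Ephrins and their receptors had a median of 0.23 (percentile 95.8), led by Ephb6 at 0.64 and Efna3 at 0.60, with Epha4 lowest at -0.64. Netrins, slits and their receptors had a median of 0.18 (percentile 87.3), with Robo1 at 0.62, Dcc at 0.59 and Unc5c at -0.85. With the floor at the 75th percentile the ephrin median was -0.07 and the netrin and slit median -0.09. Chemokines had a median of 0.03 (percentile 41.5), with Cxcl12 at -0.87. The chemokine median was below 0 after centring, quantile normalization and loess. Many receptors on these lists are also made by neurons, whose general markers had a median of 1.55 in these pools.

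The BMP and TGF-beta list had a median of 0.27 (percentile 99.3), with the antagonist gene Grem1 2.13-fold higher in the external carotid pool, a call lost with the pseudocount and at the 75th percentile floor, Bmp5 at 0.78 and Gdf10 2.52-fold higher in the internal carotid pool. The Notch list had a median of 0.27 (percentile 99.7), shares members with the arterial list, and ended within the random range, at percentile 96.4, with the median over probe sets. Wnt genes had a median of 0.10 (percentile 54.6), with Axin2 at 0.76 and Wnt5b 2.19-fold higher in the internal carotid pool, read from a probe set open to cross-hybridisation and with no value without it, a call also lost with the pseudocount and at the 75th percentile floor. Hedgehog genes had a median of -0.11 (percentile 10.7), with Gas1 at -0.82 and Ptch1 2.07-fold higher in the external carotid pool, a call lost after centring, quantile normalization and loess, with the pseudocount and at the 75th percentile floor. Fgf genes had a median of -0.07 (percentile 5.50), with Fgf10 at 0.78 and Fgf9 at -0.80. The Fgf list lay below the random range under 4 of 10 settings, and its median was 0.05 with no floor. Retinoic acid genes had a median of -0.01 (percentile 43.2), which was 0.10 with the floor at the 25th percentile and 0.20 with no floor. Cyp26b1, which degrades retinoic acid, was 4.31-fold higher in the internal carotid pool, a call lost at the 75th percentile floor.

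Pharyngeal arch patterning genes differed in both directions. Their median was 0.38 (percentile 99.98), with 4 of 29 at least 2-fold higher in the external and 2 in the internal carotid pool. In the same pools the Schwann cell and neural crest markers had a median of 0.60 and the skeletal muscle markers of -2.05. Hand1 was 4.10-fold and Foxd1 3.06-fold higher in the external carotid pool. Hand2, at 0.39, is also on the sympathetic neuron list, whose median was 2.11. Barx1 was 4.51-fold and Pitx1 2.83-fold higher in the internal carotid pool, the latter call lost with the pseudocount and at the 75th percentile floor. Hox genes of paralogue groups 1 to 5 had a median of 0.24 (percentile 82.0; 97.7 with no floor), with Hoxb3 at 0.80. Hoxa5 was 2.51-fold higher in the internal carotid pool, a call lost with the pseudocount, at the 75th percentile floor and with the median over probe sets, and its log2 ratio was 0.17, external over internal, without probe sets open to cross-hybridisation.

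Cell cycle genes had a median of -0.19 (percentile 1.12), with 22 of 29 below 0. Ccne1 was at -1.06, within 2-fold with the pseudocount, with the median over probe sets and without probe sets open to cross-hybridisation, and Plk1 at -0.99. The list lay within the random range, at percentile 3.16, with the floor at the 75th percentile. Immediate early and dissection stress genes had a median of 0.27 (percentile 99.6), with Klf2 at 1.13, within 2-fold with the pseudocount and at the 75th percentile floor, Ier2 at 0.89 and the heat shock gene Hspb1 at -1.28. Hypoxia and glycolysis genes had a median of 0.07 (percentile 74.5), with Aldoc at 0.89 and Car9 at -0.63. Ribosomal protein genes had a median of -0.36 (percentile 0.80) and oxidative phosphorylation genes of -0.21 (percentile 17.1). The ribosomal list lay below the random range under 7 of 10 settings. Its median was 0.014 after quantile normalization (percentile 53.4) and -0.03 after loess (percentile 20.35). These bright genes lie where the arrays' own trend was -0.19. The X- and Y-linked marker genes had a median of 0.02 (percentile 42.2), with Xist at 0.11 and Kdm5d at 0.24, and the median was below 0 after centring, with the median over probe sets and without probe sets open to cross-hybridisation.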

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

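The tests of endothelial share and of endothelium-restricted arterial genes were chosen after the arterial result was seen, and the members' values were known when the restricted genes were picked. Probe sets without 1 gene name were not part of the comparisons, and among 3481 of them with a ratio or bound, 34 were at least 2-fold higher in the external and 40 in the internal carotid pool. No control sample exists against which to set these counts.

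Sympathetic neuron genes were higher in the external carotid pool, with a median log2 ratio of 2.11. A brightness-dependent difference between the arrays is argued against by its size, as group medians by mean signal ran only from 0.17 to -0.19. Loess could therefore move the list little, and the median was 2.07 after it. Nerve cells carried along with the dissected vessel are a candidate source: 33 measured neuronal genes on no earlier list had a median of 0.67, 10 of them at least 2-fold higher in the external carotid pool, though the most abundant, Bex1, was at -0.58 and the next, Syt11, was at 0.70. Whether that RNA came from ganglion cell bodies, growing axons, carotid body cells or cells of the vessel stays open. So does variation between pools, with 1 array per group.

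Skeletal muscle genes were higher in the internal carotid pool, with a median of -2.05. The small range of the same brightness trend argues against a brightness-dependent difference. Loess could move this list little too, and the median was -2.02 after it. Muscle tissue carried along with the dissected vessel is a candidate source, as 30 measured muscle genes on no earlier list had a median of -0.64, and 10 of them were at least 2-fold higher in the internal carotid pool, while the most abundant, Fhl1 and Cryab, were at -0.31 and -0.27. No value separates this from a difference in the tissue next to each branch, and variation between pools stays open.

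Arterial endothelial genes had a median of 0.47 with no member past 2-fold, and after loess their median was 0.48, above the random range of -0.17 to 0.17. A larger share of endothelial cells of every kind would move both lists alike. The arterial minus venous difference was 0.78 (bootstrap over genes 0.38 to 1.005), and 0.47 (0.25 to 0.93) with the median over probe sets. Whether both lists read endothelium alone was not tested, so this difference cannot exclude a larger share as the only source. The 23 measured endothelial genes on neither list had a median of 0.18 (percentile 99.04), which goes with a larger share. The arterial minus other endothelial difference was 0.29 (0.04 to 0.51). Its interval included 0 after loess (-0.08 to 0.51) and with the median over probe sets (-0.02 to 0.38). Nerve and glial cells that also use Notch and ephrin genes remain possible: 6 measured endothelium-restricted genes had a median of 0.57, but they were picked after their values were seen, so this excludes nothing. More arterial and less venous endothelium in the external dissection, a larger endothelial share, a difference between the vessels and variation between pools all stay open.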

How the results depend on the processing

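No alternative was added after the results were seen. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The counts of genes at least 2-fold higher in the external and internal carotid pools were 1141 and 667 at 1.5-fold, 53 and 70 at 3-fold, 429 and 319 as probe sets, 761 and 474 with the floor at the 25th percentile, 85 and 99 at the 75th, and 1485 and 1081 with no floor. They were 160 and 128 with a pseudocount, 217 and 150 with the median over probe sets, and 249 and 177 without probe sets open to cross-hybridisation. Thresholds and floors change these counts by construction. Of 389 list medians under alternatives, 386 stayed within the technical spread of 0.34. That is a spread of single genes and is wide for a list median, so the count says little about stability. The ephrin, netrin and slit, and fibroblast medians changed sign within it, and the fibroblast list ran from percentile 12.9 to 85.5. The ribosomal median was 0.014 after quantile normalization, the tendon median 0.46 with the floor at the 25th percentile, and the thyroid, parathyroid and thymus median 0.059 after quantile normalization. Measured members went from 10 to 12 for the tendon list and from 4 to 6 for the thyroid list, and stayed at 30 for the ribosomal list. With the same 4 members the thyroid median was 0.31 after loess. The cause was not tested further. Of 2023 named-gene values, 1849 stayed within that spread, and 173 went beyond it without a change of sign in a gene called at 2-fold. Calls were lost among both kinds of value, as for Ecel1 after centring and Prph with the median over probe sets. Hoxa5 reversed to 0.17 without probe sets open to cross-hybridisation, where another probe set stands for it. Edn3 ranged from 0.08 to 0.24, with no value at the 75th percentile floor, and Ednrb from 0.79 to 1.23. The sympathetic, general neuronal, Schwann cell, skeletal muscle, macrophage, arterial, arch patterning, BMP and TGF-beta, elastic matrix and immediate early lists lay outside the random range under all 10 settings, and the endothelial list under 9, with percentile 96.7 after loess. Signals near the floors limit Edn3, Edn2 and every bound. They also limit the size of large folds whose lower signal was near its floor, such as those of Cartpt, Th and Dpt.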

Other observations

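The granulocyte genes described here were chosen after their own values had been seen, so they give no independent check on S100a8 and Ngp. Leaving S100a8 and Ngp out, 12 measured granulocyte genes had a median log2 ratio of -0.59, with 3 at least 2-fold higher in the internal carotid pool and none in the external carotid pool. Among them Mpo was at -1.20 and Ltf at -1.20, S100a9 had a bound of -1.28, and Hp was at 0.76, Anxa1 at 0.74 and Mmp9 at 0.59. The macrophage list moved the same way, with a median of -0.51. The erythroid list, also from blood, had -0.12, with 12 of 14 measured members below 0, and the difference between these lists was not tested.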
